A study of Mus musculus with 9 samples.

How the data were processed

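RNA from mouse retinas was measured by bulk RNA sequencing in 9 libraries, 3 in each of 3 groups. Normoxic libraries came from mice kept in room air. PBS libraries came from mice with oxygen-induced retinopathy (OIR, a model in which high oxygen stops retinal vessel growth and the return to room air is followed by abnormal new vessels) that received phosphate-buffered saline into the vitreous. Gel libraries came from OIR mice that received a hydrogel, PCC1/PHCF in the labels, releasing procyanidin C1 (PCC1), a plant polyphenol that the title of the series presents as removing senescent cells selectively. The labels place the injection at postnatal day 15 and the retina collection at postnatal day 17. They do not say that the Normoxic mice were injected, so PBS and Normoxic libraries differ in oxygen history and possibly in injection. No library came from a hydrogel without PCC1, so comparisons with Gel cover the drug and its carrier together. All libraries carry the same batch date. The labels do not say that the replicates of a group are separate animals, so every p-value here measures only the spread between these samples.

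The deposited count table holds whole numbers per gene and library, and per the submitters' processing notes Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the genome build GRCm39 were used, with no role given for any of them. Whether the counts are rounded RSEM estimates is not given in the sources used here. The deposited FPKM table was made by the authors. Each FPKM value equals the count divided by the library total and by a single length per gene, with a relative spread of at most 2.9e-10 between libraries and 0 genes that were 0 in one table only. The FPKM values therefore hold no measurement beyond the counts, and served for gene length and for an alternative. Genes are identified by symbol and Entrez number, and no coordinates are given because the reference annotation used here is of another build. The table lists 26683 genes. Total counts ran from 29324142 to 35663470 per library, so 1 CPM (a count scaled to the library total, in parts per 1e+06) rests on about 30 counts.

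Counts were analysed in R 4.3.3. Genes with low counts were removed with filterByExpr of edgeR 4.0.16 (minimum count 10), which kept 17362 genes (65.1%). Libraries were scaled by the trimmed mean of M values (TMM). The 3 pairwise comparisons used the edgeR quasi-likelihood F test fitted to all 9 libraries with group as the only term, and p-values were adjusted over all kept genes by the Benjamini-Hochberg method. A gene is called higher or lower where this adjusted p is under 0.05. The common dispersion was 0.0312. Standard errors (SE) of log2 fold changes are the log2 fold change divided by the square root of its F statistic. CPM are given as mean ± SD over 3 libraries.

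Of 40 gene lists written for this tissue and treatment, 38 had at least 3 kept genes. The lists of neutrophil genes and of sex-linked genes did not. Each of the 38 was tested with camera (limma 3.58.1, two-sided) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and p-values were adjusted over the lists. The estimated correlation and fry served as alternatives. With an estimated correlation, 4 lists were called in PBS versus Normoxic (sprouting and tip cell genes, bipolar cell genes, complement and acute phase genes, extracellular matrix genes), 0 in Gel versus PBS and 1 in Gel versus Normoxic (complement and acute phase genes). Several lists share genes, so their tests are not independent. Counts of called list members are given over all kept genes and, separately, adjusted over the list alone.

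Genes to be named followed a rule: in each comparison the 8 largest increases and 8 largest decreases among called genes with a mean of at least 1 CPM, a symbol that is not a gene model, and CPM that did not overlap between the groups. The rule adds up to 4 members with the smallest p from each list, and always a panel of 10 genes that holds Vegfa, Gfap, Cdkn1a, Cdkn2a, Il1b, Il6, Tnf and Pecam1. Some genes the rule allows, among them 2 of the panel, are not described in the text. Where fewer than 5 genes were called, the 5 with the smallest p and a mean of at least 1 CPM are named as not past the threshold. From the genes this rule allows, those printed were picked after their values were seen, and so were genes named only because few of a list were called. The groups, the comparisons, the tests, the lists, the rule and most alternatives were fixed before the data were examined.

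The test was tried on simulated data with each gene's mean over all 9 libraries, its spread and the library sizes. A true 2-fold change was called for 56.7%, 58.2% and 53.7% of changed genes in PBS versus Normoxic, Gel versus PBS and Gel versus Normoxic, a 4-fold change for 90.9%, 89.4% and 86.4%, and a 1.5-fold change for 16.4%, 10.4% and 17.9%. False calls made up 4.39%, 6.25% and 1.87% of the calls.

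The alternatives were size factors by relative log expression, no filter, a filter of a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom with sample weights, only the 6 libraries compared, a block on the replicate number, a minimum log2 fold change of 1, limma-trend on the log2 of FPKM plus 1, a prior count of 0.5, and each library left out in turn. After the data were examined, 3 were added: removal of each library's trend on gene length (loess, span 0.3), the same with the block, and 1 surrogate variable. The share of oppositely changed genes was compared with 30 simulated data sets. Terms of the pathway annotation in the deposited table were tested for enrichment with a one-sided Fisher's exact test. Il6 was not analysed here, and Cdkn2a, Il1b and Tnf were left out of the test by the filter.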

Results

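The data are RNA fragment counts per gene from 9 mouse retina libraries, 3 per group. The total counts of replicates 1, 2 and 3 were 29324142, 32505324 and 30616274 in Normoxic, 31390727, 29346869 and 35542587 in PBS, and 29705600, 35663470 and 33713974 in Gel. Counting intervals given here cover counting error only, not differences between animals or preparations. The libraries separated along the first principal component, which held 38.6% of the variance: the 3 Normoxic libraries lay at -43.8 to -35.8, PBS replicates 1 to 3 at 21.5, 11.7 and 58.3, and Gel replicates 1 to 3 at -13.3, 18.3 and 20. PBS 3 lay farthest from Normoxic and Gel 1 was the injected library nearest to it. The libraries also differed in how counts varied with gene length. The Spearman correlation across genes between gene length and a library's difference from the other libraries of its group was -0.49 in PBS 3, 0.32 in PBS 1, 0.41 in PBS 2, 0.32, -0.29 and -0.20 in Gel 1 to 3, and -0.05 to 0.03 in Normoxic (genes are not independent replicates). Ribosomal protein genes took 2.73% of the counts in PBS 3 and 1.14% to 1.72% in the other 8 libraries.

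**Figure D1:**
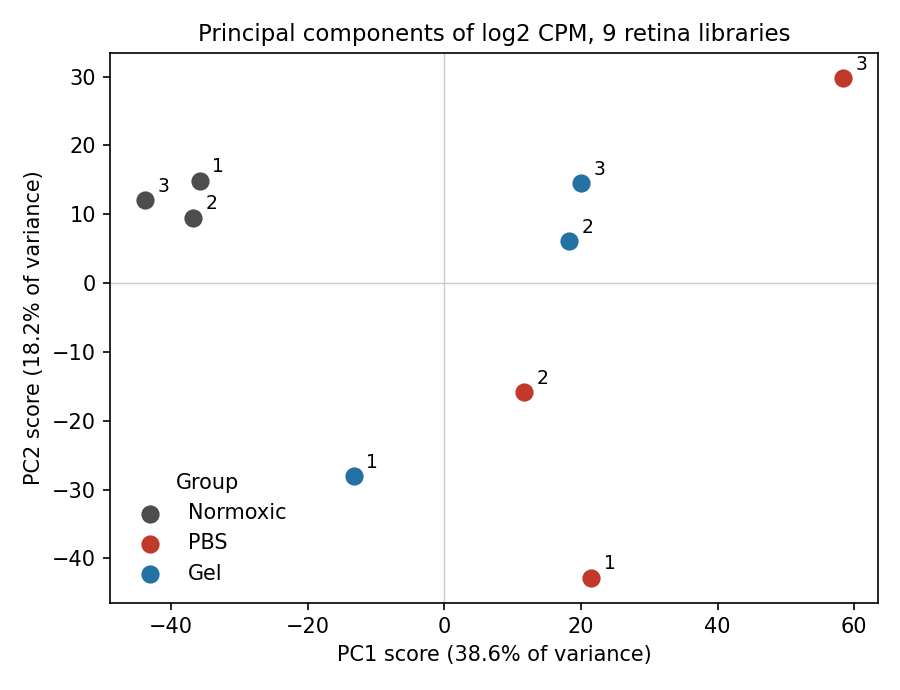
Principal components 1 (38.6% of the variance, horizontal) and 2 (18.2%, vertical) of log2 CPM of the 17362 kept genes, with 1 point per library coloured by group and labelled by replicate. The Normoxic libraries sit together at the left, between -43.8 and -35.8 on component 1, while PBS and Gel libraries spread over both components.

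PBS and Normoxic retinas were compared to see what OIR, together with an injection of saline, changes. The largest increases were Edn2 (Entrez 13615), which encodes the peptide endothelin 2, at 31.2 ± 23.2 CPM in PBS and 0.171 ± 0.0902 CPM in Normoxic (SD, n = 3), Esm1, Lad1 (log2 fold change 5.18 ± 0.54, SE), Serpina3n (4.85 ± 0.41), Fgf2os (4.68 ± 0.66), C4b (4.57 ± 0.35), Bcl3 (4.25 ± 0.71) and Hmox1 (4.25 ± 0.44). Without PBS 1 the log2 fold changes were smaller for Edn2 (7.47 to 6.74), Lad1 (to 4.46), Serpina3n (to 4.20), Hmox1 (to 3.53) and Bcl3 (to 3.44), and without Normoxic 2 that of Fgf2os was larger (6.20). The largest decreases were BC055402 (Entrez 407809), at 2.93 ± 1.28 CPM in PBS and 19.8 ± 2.94 CPM in Normoxic, P2rx2 (-2.56 ± 0.35), a channel gated by extracellular ATP, Atp13a5 (-2.43), Bfsp2 (-2.08), a lens filament gene, Ttn (-1.87), Il20ra (-1.80), Crispld1 (-1.74) and Actn2 (-1.70), whose product crosslinks actin. The edgeR adjusted p was 0.000132 to 0.0454 for these 16 genes. Fgf2os is transcribed antisense to Fgf2, which rose as well (2.54 ± 0.26), and the strand of the reads is not given in the sources used here. In all, edgeR called 1101 of 17362 genes, 748 higher and 353 lower (67.9% higher), with 599 at a log2 fold change of at least 1 in size and 3711 at an unadjusted p under 0.05. In 29.2% of all genes the 3 PBS values did not overlap the 3 Normoxic values, where chance gives 10%. The CPM of every called gene named for this comparison were free of overlap except Hbb-bs. Leaving out Normoxic 1, 2 or 3 lowered the number of calls to 475 (78.1% higher), 455 (81.8%) and 494 (82.0%), and the share higher was 57.9% with limma-voom. Leaving out 1 library ended the edgeR calls of Ttn (any Normoxic library, PBS 1, PBS 3 or Gel 3, adjusted p up to 0.115), Il20ra (any library but PBS 2, up to 0.167), Crispld1 (Normoxic 1, Normoxic 2 or PBS 1, up to 0.0878) and Actn2 (Normoxic 1, Normoxic 3 or PBS 1, up to 0.0699).

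Vessel genes were higher in PBS. Esm1 (Entrez 71690), a marker of endothelial tip cells, had 382 counts over the PBS libraries and 1 over the Normoxic libraries, a count ratio of 370 (95% counting interval 66.0 to 14600, edgeR adjusted p = 0.000202). Angpt2, which loosens endothelial contacts with pericytes, rose 4.22-fold (5.03 ± 0.732 to 21.3 ± 6.28 CPM, SD, n = 3), Igfbp3 rose 4.24-fold and Col4a1, a basement membrane collagen, rose 2.92-fold (edgeR adjusted p at most 0.000773). Acta2 (Entrez 11475), smooth muscle actin, rose 10.8-fold (2.98 ± 0.258 to 32.2 ± 8.85 CPM), and Tagln, also of smooth muscle, rose 4.81-fold. Of 22 sprouting and tip cell genes, 15 rose (18 adjusted over the list alone), with a median log2 fold change of 1.38 and a camera adjusted p = 5.41e-17 (adjusted p = 0.047 with an estimated correlation). Of 14 pericyte and smooth muscle markers, 6 rose (12 adjusted over the list alone). Their median was 0.70, with a camera adjusted p = 3.99e-09 (0.064 as adjusted p with an estimated correlation). Of 22 endothelial cell markers, 9 rose and 1 fell (11 and 2 adjusted over the list alone). Their median was 0.66, with a camera adjusted p = 8.41e-05 (adjusted p = 0.27 with an estimated correlation). The risers included Pecam1 (Entrez 18613), an endothelial adhesion molecule (log2 fold change 0.88 ± 0.17, edgeR adjusted p = 0.014), and Emcn (1.88 ± 0.28), and the one that fell was Kdr, the main endothelial receptor of VEGF (142 ± 8.34 and 198 ± 18.5 CPM, -0.48, edgeR adjusted p = 0.0313). The mean of the endothelial list relative to Normoxic was 0.11 in PBS 1, 0.39 in PBS 2 and 0.77 in PBS 3. Without 1 library, edgeR no longer called Pecam1 (Normoxic 1 or 2, adjusted p up to 0.0691) and Kdr (any Normoxic library, PBS 1 or Gel 3, up to 0.156).

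Glial reactivity genes rose together in PBS. Gfap (Entrez 14580), an intermediate filament that reactive Müller glia and astrocytes make, rose 12.3-fold (21.6 ± 5.29 to 266 ± 88.7 CPM, SD, n = 3, edgeR adjusted p = 0.000132), and the protease inhibitors Serpina3n and A2m rose 28.9-fold and 13.7-fold. Of 21 Müller glia and astrocyte reactivity genes, 18 rose (20 adjusted over the list alone). Their median was 2.33, with a camera adjusted p = 2.75e-20 (adjusted p = 0.064 with an estimated correlation). The mean of this list relative to Normoxic was 3.14, 2.28 and 2.03 in PBS 1, 2 and 3. Of 8 retinal astrocyte markers, 4 rose (6 adjusted over the list alone): Gfap, Pdgfra (0.86 ± 0.13), Cd9 (1.14 ± 0.18) and Aldh1l1 (0.72 ± 0.17). The list had a median of 0.79 and a camera adjusted p = 8.41e-05 (adjusted p = 0.064 with an estimated correlation). Of 15 Müller glia homeostatic markers, Aldh1a1 rose (1.11 ± 0.27), while Aqp4, the water channel of glial endfeet (-0.66 ± 0.10), and Kcnj10, their potassium channel (-0.46 ± 0.12), fell, giving 1 riser and 2 fallers (2 and 4 adjusted over the list alone). The median of that list was -0.07 and its mean 0.04, and camera gave an adjusted p = 0.464 in the lower direction. Calls by edgeR that ended without 1 library were those of Aldh1a1 (any Normoxic library, PBS 2, PBS 3 or Gel 2, adjusted p up to 0.143), Kcnj10 (any library but PBS 2, up to 0.198) and Aldh1l1 (Normoxic 1, Normoxic 3 or PBS 1, up to 0.0897). Removing the length trend also ended the call of Kcnj10 (0.0789 by edgeR, in a range of 0.0124 to 0.198 over all alternatives).

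Genes of microglia, complement and the interferon response were higher in PBS. Csf1r, the growth factor receptor of microglia, rose from 14.3 ± 1.14 to 32.6 ± 4.64 CPM (SD, n = 3) and C1qb, a part of the complement initiator C1q, rose 4.98-fold. C3, the central complement component, rose 4.76-fold and B2m, the light chain of MHC class I, 4.12-fold (17.5 ± 1.25 to 72.1 ± 16.9 CPM), all with edgeR adjusted p of at most 0.000867. C4b counts may include its near-identical neighbour C4a. Of 25 microglia and macrophage markers, 20 rose (22 adjusted over the list alone). Their median was 1.73, with a camera adjusted p = 1.87e-19 (adjusted p = 0.064 with an estimated correlation). Of 18 complement and acute phase genes, 12 rose (16 adjusted over the list alone). Their median was 2.24, with a camera adjusted p = 1.82e-16 (adjusted p = 0.047 with an estimated correlation). Of 25 interferon response genes, 22 rose (23 adjusted over the list alone), among them Ifit1 (2.11 ± 0.33) and the peptide transporter Tap1 (1.42 ± 0.21). The list had a median of 1.69 and a camera adjusted p = 4.77e-18 (adjusted p = 0.13 with an estimated correlation). The interferon list stood at -0.59 in Normoxic 3 and at 0.30 and 0.29 in the other Normoxic libraries, relative to the group mean. Of 14 inflammatory cytokine and NF-kB genes, 7 rose (9 adjusted over the list alone). Their median was 0.85, with a camera adjusted p = 3.92e-05 (adjusted p = 0.092 with an estimated correlation), among them the adhesion molecule Icam1 (1.97 ± 0.37), whose edgeR call ended without Normoxic 1 or Normoxic 2 (adjusted p up to 0.0604). Of 3 lymphocyte genes, Cd8a rose (2.10 ± 0.33), with a list median of 0.11 and a camera adjusted p = 0.264.

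Matrix and cell division genes were higher in PBS. Tgfbi, a matrix protein induced by TGF-beta, rose 7.81-fold (0.873 ± 0.0765 to 6.84 ± 1.15 CPM, SD, n = 3), Timp1, an inhibitor of matrix proteases, 8.58-fold, and Mki67, a marker of cycling cells, 9.47-fold (0.416 ± 0.161 to 3.99 ± 0.531 CPM), with edgeR adjusted p of 0.000152, 0.00217 and 0.000738. Top2a, needed for chromosome separation, rose 14.8-fold. Of 25 extracellular matrix genes, 16 rose (17 adjusted over the list alone). Their median was 1.04, with a camera adjusted p = 9.22e-13 (adjusted p = 0.047 with an estimated correlation). Of 22 cell proliferation genes, 10 rose (16 adjusted over the list alone). Their median was 1.29, with a camera adjusted p = 8.36e-12 (adjusted p = 0.064 with an estimated correlation). Of 9 fibroblast and scleral genes, Col1a1 (2.48 ± 0.50), Col3a1 (1.44 ± 0.21) and Pdgfra rose (5 adjusted over the list alone). Their median was 0.86, with a camera adjusted p = 5.9e-05 (adjusted p = 0.16 with an estimated correlation). The edgeR call of Col1a1 ended without any 1 Normoxic library (adjusted p up to 0.077).

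Some hypoxia and stress genes were higher in PBS. Ndufa4l2 (Entrez 407790), a HIF target of mitochondria, rose 14.0-fold (6.25 ± 1.48 to 87.4 ± 21.6 CPM, SD, n = 3, edgeR adjusted p = 4.53e-05), and Adm, a vessel-dilating peptide induced by hypoxia, rose 11.4-fold. Vegfa (Entrez 22339), the main growth factor of new vessels, was at 441 ± 189 CPM in PBS and 255 ± 31.4 CPM in Normoxic, a log2 difference of 0.79 ± 0.25 that did not pass the test (edgeR adjusted p = 0.0919, 0.0116 without PBS 3, range 0.0116 to 0.264 over the alternatives). Of 26 hypoxia and HIF target genes, 6 rose (9 adjusted over the list alone). Their median was 0.33, with a camera adjusted p = 0.000324 (adjusted p = 0.36 with an estimated correlation). The mean of that list was 1.22 in PBS 1, 0.40 in PBS 2 and 0.65 in PBS 3, and its camera call was lost without PBS 1 (median 0.22, adjusted p = 0.141). Of 20 NRF2 antioxidant genes, 5 rose (5 adjusted over the list alone): Hmox1, which degrades heme, the metal-binding Mt1 (2.15 ± 0.21) and Mt2 (13.0 ± 1.19 to 127 ± 39.4 CPM), Gstm1 (1.00 ± 0.22) and Osgin1 (1.22). The list had a median of 0.27 and a camera adjusted p = 6.95e-05 (adjusted p = 0.31 with an estimated correlation). Of 19 unfolded protein and integrated stress genes, Atf3 (2.10 ± 0.25), Trib3 (0.78 ± 0.15), Ddit3 (0.72 ± 0.14) and Atf5 (0.67 ± 0.15) rose, 4 in all (7 adjusted over the list alone). Their median was 0.40, with a camera adjusted p = 5.68e-05 (adjusted p = 0.064 with an estimated correlation). The edgeR calls that 1 library could end were those of Gstm1 (any Normoxic library, adjusted p up to 0.0764), Osgin1 (any library but PBS 2 and Gel 1, up to 0.149), Trib3 (Normoxic 1 or 3, up to 0.0653), Ddit3 (Normoxic 1 or 2, up to 0.0795) and Atf5 (Normoxic 1, Normoxic 2, PBS 1 or Gel 2, up to 0.135). The call of Atf5 also ended with the length trend removed (0.0959 by edgeR, range 0.00377 to 0.135).

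Genes of inner retinal neurons were lower in PBS, by less than 2-fold. Slc6a9, the glycine transporter of amacrine cells, fell from 372 ± 12.1 to 239 ± 19.2 CPM (SD, n = 3), and Gad1, which makes GABA, fell from 353 ± 8.69 to 235 ± 16.0 CPM (edgeR adjusted p = 0.00609 and 0.0089). Grik1, a glutamate receptor subunit of some bipolar cells, fell from 111 ± 1.80 to 77.7 ± 5.33 CPM. Of 16 amacrine cell genes, 5 fell (11 adjusted over the list alone), among them also Tfap2c (-0.57) and Slc17a8 (-0.52). The list had a median of -0.31 and a camera adjusted p = 4.71e-07 (adjusted p = 0.064 with an estimated correlation). Of 17 bipolar cell genes, 4 fell (7 adjusted over the list alone), among them Grik1 (-0.52), Tacr3 (-0.62) and Lrtm1 (-0.46), median -0.30, camera adjusted p = 2.35e-05 (adjusted p = 0.047 with an estimated correlation). Of 16 retinal ganglion cell genes, the neurofilaments Nefm (-0.59) and Nefh (-0.48) and the transcription factor Ebf3 (-0.42) fell, 3 in all (3 adjusted over the list alone). Their median was -0.18, with a camera adjusted p = 0.00566 (adjusted p = 0.36 with an estimated correlation). Of 9 horizontal cell genes, Lhx1 fell (-0.84), with a median of -0.26 and a camera adjusted p = 0.0933 (0.0185 without PBS 2). Log2 fold changes fell with gene length across genes (Spearman -0.30). Leaving out 1 library ended the edgeR calls of Nefm (Normoxic 3, adjusted p = 0.0539), Lhx1 (any Normoxic library or PBS 1, up to 0.0799), Tacr3 (those 4 or PBS 2, up to 0.109), Tfap2c (those 4 or PBS 3, up to 0.138), and, without any Normoxic library and some others, Slc17a8 (PBS 1, PBS 3, Gel 2 or Gel 3, up to 0.121), Lrtm1 (PBS 2, Gel 2 or Gel 3, up to 0.138), Ebf3 (PBS 1, PBS 3 or Gel 3, up to 0.145) and Nefh (PBS 1, PBS 2, Gel 2 or Gel 3, up to 0.168). Removing the length trend also ended the call of Ebf3 (0.0605 by edgeR, in a range of 0.00506 to 0.145).

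Photoreceptor genes changed little in PBS. Of 19 rod photoreceptor genes, edgeR called 0, with 2 at an unadjusted p under 0.05 and 1 called by DESeq2 and by limma-voom, and the median was 0.13 (camera adjusted p = 0.103). Of 14 cone photoreceptor genes, Gnb3, a subunit of the phototransduction G protein, rose (461 ± 27.3 to 717 ± 125 CPM, SD, n = 3, edgeR adjusted p = 0.0157), with a list median of 0.31 and a camera adjusted p = 0.0169 (adjusted p = 0.36 with an estimated correlation). The rod list mean relative to Normoxic was 0.03, -0.03 and 0.44 in PBS 1, 2 and 3, the oxidative phosphorylation mean -0.08, -0.05 and 0.76. Without PBS 3 the rod median was -0.05 and the cone call was lost (median 0.18, camera adjusted p = 0.0724). Without PBS 2 the rod list passed camera (median 0.18, adjusted p = 0.0185). The edgeR call of Gnb3 ended without any 1 Normoxic library (adjusted p up to 0.0834).

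Senescence and survival genes were examined because the hydrogel is meant to clear senescent cells. Cdkn1a (Entrez 12575), the cell cycle inhibitor p21, rose 3.40-fold in PBS (8.29 ± 0.846 to 28.2 ± 7.89 CPM, SD, n = 3, edgeR adjusted p = 0.000743). Cdkn2a, which encodes p16, had 1, 1 and 1 counts in the Normoxic libraries, 19, 2 and 16 in PBS and 1, 4 and 3 in Gel, too few for the test. Il1b had 1, 0 and 0 counts in Normoxic, 0, 2 and 4 in PBS and 1, 2 and 0 in Gel, and Tnf 0, 0 and 2, then 2, 0 and 5, then 0, 1 and 0. Of 16 senescence and cell cycle inhibitor genes, 6 rose in PBS (7 higher and 1 lower adjusted over the list alone). Their median was 0.29, with a camera adjusted p = 0.000148 (adjusted p = 0.12 with an estimated correlation). Of 21 secretory phenotype factors, 9 rose (14 higher and 1 lower adjusted over the list alone). Their median was 0.72, with a camera adjusted p = 5.25e-07 (adjusted p = 0.092 with an estimated correlation). Of 22 p53 target genes, Cdkn1a, Phlda3 (1.28 ± 0.21) and the death receptor Eda2r (4.16 ± 1.00) rose (6 adjusted over the list alone). Their median was 0.13, with a camera adjusted p = 0.0135 (adjusted p = 0.26 with an estimated correlation). Eda2r, at 0.067, 0 and 0 CPM in Normoxic, ranged from 3.62 to 6.88 over the alternatives. Of 8 survival genes, Bcl2a1b (BCL-2 family, 3.60 ± 0.65) and Birc3 (2.07 ± 0.42) rose. Adjusted over the list alone 3 were higher and 1 lower (list median 0.14, camera adjusted p = 0.11). Of 19 pro-apoptotic genes, Casp8 rose (1.81 ± 0.35; 2 adjusted over the list alone). Their median was 0.27, with a camera adjusted p = 0.018 (adjusted p = 0.16 with an estimated correlation). Without PBS 3 the camera calls of the p53 list (median 0.04, adjusted p = 0.057) and the pro-apoptotic list (median 0.12, adjusted p = 0.0901) were lost. Without 1 library, edgeR no longer called Eda2r (any Normoxic library, PBS 1 or PBS 3, adjusted p up to 0.136), Bcl2a1b (Normoxic 3, 0.0525), Birc3 (Normoxic 1 or 2, up to 0.0805) and Casp8 (Normoxic 1, 0.0519).

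Genes of sterol synthesis were lower in PBS, and so were Per2, a repressor in the circadian clock (44.5 ± 1.11 to 23.1 ± 5.24 CPM, SD, n = 3, edgeR adjusted p = 0.0138), and Dusp1, a phosphatase that ends MAP kinase signals (37.1 ± 4.70 to 19.6 ± 4.21 CPM). Of 18 cholesterol synthesis genes, 3 fell (8 adjusted over the list alone). Their median was -0.26, with a camera adjusted p = 2.81e-05 (adjusted p = 0.26 with an estimated correlation). Of 15 circadian clock genes, Per2 fell (-0.95; 1 higher and 1 lower adjusted over the list alone), median -0.12, camera adjusted p = 0.103. Of 18 immediate early genes, Dusp1 fell (-0.92; 1 higher and 3 lower adjusted over the list alone), with a median of 0.06, a mean of -0.07 and a camera adjusted p = 0.382 in the lower direction. Of 23 oxidative phosphorylation genes edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom (median 0.30, camera adjusted p = 0.077), and of 12 mitochondrially encoded genes likewise 0 by each (median 0.15, camera adjusted p = 0.302). The oxidative phosphorylation list passed camera without PBS 1 (median 0.45, adjusted p = 0.00436) or PBS 2 (0.41, 0.00608) and had a median of -0.08 without PBS 3, and the mitochondrial list passed without PBS 1 (0.35, 0.042) and had a median of -0.13 with the length trend removed. Calls by edgeR that ended without 1 library were those of Per2 (any Normoxic library, adjusted p up to 0.0618) and Dusp1 (Normoxic 1, Normoxic 2, PBS 1 or PBS 2, up to 0.0824).

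Markers of blood and nearby tissues were also measured. Of 5 erythrocyte genes, the hemoglobin gene Hbb-bs rose in PBS (70.3 ± 45.6 and 23.0 ± 2.80 CPM, SD, n = 3, edgeR adjusted p = 0.0495; 5 adjusted over the list alone). Their median was 1.45, with a camera adjusted p = 0.00858 (adjusted p = 0.36 with an estimated correlation). The list mean was 1.60 in PBS 1, -0.03 in PBS 2 and 2.04 in PBS 3, and the edgeR call of Hbb-bs ended without any 1 library but PBS 2 (adjusted p up to 0.172, 0.0948 without PBS 3). Hemoglobin genes have near-identical copies whose counts may not be separable. Of 13 lens genes, Cryab, a small heat shock protein, rose (0.92 ± 0.21) and Bfsp2 fell, median -0.81, camera adjusted p = 0.231 (0.0252 without Normoxic 1, 0.00804 without Normoxic 3, and a median of 0.75 without Normoxic 2). The edgeR call of Cryab ended without any 1 Normoxic library (adjusted p up to 0.122). Of 15 retinal pigment epithelium and melanocyte genes edgeR called 0, with 3 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom, median 0.69, camera adjusted p = 0.11 (0.00482 without Normoxic 1, 0.00873 without PBS 1). The mean of that list was -0.13, 0.26 and 1.58 in PBS 1, 2 and 3, and 0.75, 0.02 and -0.77 in Normoxic 1, 2 and 3. Of 3 corneal and conjunctival epithelium genes (median -0.14, camera adjusted p = 0.716) and 4 skeletal muscle genes (median 0.25, camera adjusted p = 0.368) edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom.

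Gel and PBS retinas were compared to see what the PCC1 hydrogel changes in OIR retinas. The 5 genes with the smallest p did not pass the threshold. BC055402 was at 12.2 ± 1.50 CPM in Gel and 2.93 ± 1.28 CPM in PBS (SD, n = 3), Acta2 at 7.68 ± 2.95 and 32.2 ± 8.85 CPM, Tagln at 4.31 ± 1.06 and 15.4 ± 4.45 CPM, Hmox1 at 7.73 ± 0.393 and 48.2 ± 33.5 CPM, and Prss56, a serine protease linked to eye size, at 14.6 ± 4.94 and 60.4 ± 17.5 CPM. Their log2 differences were 2.06 ± 0.28, -2.06 ± 0.28, -1.83 ± 0.26, -2.64 ± 0.40 and -2.05 ± 0.32 (SE), with edgeR adjusted p of 0.117, 0.117, 0.117, 0.166 and 0.179. Each of the 5 was called in PBS versus Normoxic with the opposite sign, Prss56 with a log2 fold change of 2.40 (edgeR adjusted p = 0.00225). In all, edgeR called 0 of 17362 genes, with 961 at an unadjusted p under 0.05 where chance gives 868, and 8.6% of genes did not overlap where chance gives 10%. DESeq2 called 60 genes (10 higher, 50 lower), limma-voom 11 and limma-trend on FPKM 0, and edgeR called 24 with no filter and 3 with the length trend removed (Acta2, BC055402 and Tagln, adjusted p = 0.0422 each, in ranges of 3.85e-09 to 0.711, 1.74e-09 to 0.711 and 3.85e-08 to 0.711 over the alternatives). Without PBS 1 edgeR called 2 genes (BC055402 and Hmox1), without PBS 2 12, and without PBS 3 6 (Acta2, BC055402, Bcl3, Gm13821, Hmox1 and Pcolce). The adjusted p of Hmox1 ranged from 3.85e-09 to 0.742.

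Glial, hypoxia, sprouting and pericyte lists were lower in Gel than in PBS by camera, with 0 of their genes called by edgeR over all genes. Of the glial reactivity, hypoxia, sprouting and pericyte genes 18, 15, 9 and 5 had an unadjusted p under 0.05, DESeq2 called 8, 3, 4 and 3 (among them Gfap, Serpina3n, Steap4, Lcn2, Ndufa4l2, Esm1, Angpt2, Adm, Acta2 and Tagln), and limma-voom 1, 1, 0 and 2. Gfap was at 106 ± 18.2 CPM in Gel and 266 ± 88.7 CPM in PBS (SD, n = 3, -1.33 ± 0.24, edgeR adjusted p = 0.299), Serpina3n differed by -1.70 ± 0.34 and Ndufa4l2 by -1.19 ± 0.19 (38.2 ± 2.43 and 87.4 ± 21.6 CPM). Of the glial reactivity genes 16 were lower and 2 higher adjusted over the list alone, median -0.83, camera adjusted p = 3.35e-10 (adjusted p = 0.22 with an estimated correlation). The 2 higher were Steap4, a metal reductase (2.46 ± 0.46), and Lcn2, an iron-binding acute phase protein at 38.8 ± 19.0 CPM in Gel and 15.6 ± 4.82 CPM in PBS. Hypoxia genes had a median of -0.45 with 7 lower adjusted over the list alone (camera adjusted p = 7.73e-11), sprouting genes -0.26 with 6 lower (1.35e-05), pericyte and smooth muscle markers -0.25 with 3 lower (Acta2, Tagln and Des, 0.000199) and astrocyte markers -0.40 with 1 lower (Gfap, 4.01e-05). Each of these had an adjusted p = 0.22 with an estimated correlation. Esm1 differed by -2.04 ± 0.39, Angpt2 by -1.03 ± 0.21, Adm by -1.93 ± 0.47 and Vegfa by -0.64 ± 0.25 (edgeR adjusted p of 0.303, 0.336, 0.576 and 0.821). The endothelial list had a median of 0.08 (camera adjusted p = 0.376), -0.02 without PBS 1, and 0.23 without PBS 3, when it passed (adjusted p = 0.0104), and Pecam1 differed by -0.07 ± 0.17 (0.17 without PBS 3). The Müller homeostatic list had a median of 0.07 (camera adjusted p = 0.151) and passed without PBS 3 (0.18, 0.00627) or Gel 1 (0.16, 0.00393). Without PBS 2 edgeR called, among the genes named here, Acta2 (0.0151), Tagln (0.0111), Ndufa4l2 (0.0172, range 4.78e-05 to 0.749) and Angpt2 (0.0371, range 0.00378 to 0.949), and without PBS 3 Acta2 (0.0426).

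Interferon, matrix and proliferation lists were also lower in Gel, and the sterol list higher. Of the interferon response genes 10 were lower adjusted over the list alone, median -0.68, camera adjusted p = 3.31e-14 (adjusted p = 0.22 with an estimated correlation). Cxcl10, a chemokine induced by interferon, differed by -1.98 ± 0.61 (SE, n = 3, edgeR adjusted p = 0.65) and B2m by -0.60 ± 0.17 (47.5 ± 7.92 and 72.1 ± 16.9 CPM). Microglia markers had a median of -0.39 with 0 called by edgeR adjusted over the list alone, 6 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom (camera adjusted p = 6.09e-06, and 0.3 as adjusted p with an estimated correlation), Lgals3 at -1.29 and the lysosomal Cd68 at -0.76 among them. Complement genes had a median of -0.46, 2 higher (Lcn2 and C3, 0.72 ± 0.23) and 6 lower adjusted over the list alone (camera adjusted p = 0.00411, and 0.24 as adjusted p with an estimated correlation). Matrix genes had a median of -0.27 (3 lower adjusted over the list alone, Bgn, Loxl2 and Col3a1; camera adjusted p = 4.58e-05), proliferation genes -0.61 (2 lower, Ccnb2 at -1.47 and Mki67 at -1.15; 5.43e-06) and fibroblast genes -0.70 (2 lower, Col3a1 and Prelp; 7.18e-05), each with an adjusted p = 0.22 with an estimated correlation. Timp1 differed by -1.38 ± 0.37. Cholesterol synthesis genes had a median of 0.28 with 6 higher adjusted over the list alone and a camera adjusted p = 2.35e-10 (adjusted p = 0.22 with an estimated correlation). NRF2 genes had a median of -0.19 (2 lower adjusted over the list alone, Hmox1 and Mt2; camera adjusted p = 0.000985, and 0.45 as adjusted p with an estimated correlation), a call lost without PBS 3 (-0.01, 0.489) or Gel 1 (-0.06, 0.152). NF-kB genes had a median of -0.25 (camera adjusted p = 0.0427, and 0.4 as adjusted p with an estimated correlation), a call lost without PBS 1 (0.288), Gel 1 (0.0628) or Gel 2 (0.186).

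Of the senescence and survival lists, camera called the secretory phenotype factors lower in Gel than in PBS. Cdkn1a was at 26.2 ± 2.43 CPM in Gel and 28.2 ± 7.89 CPM in PBS (SD, n = 3, -0.11 ± 0.19, edgeR adjusted p = 0.987, 0.09 without PBS 3). Cdkn2a had 19, 2 and 16 counts in PBS and 1, 4 and 3 in Gel, too few for the test. The senescence list had a median of -0.12 with 3 members at an unadjusted p under 0.05 and 0 called by edgeR, DESeq2 and limma-voom (camera adjusted p = 0.24). Without PBS 2 it passed camera (-0.26, 0.00656) and without PBS 3 its median was 0.08. Secretory phenotype factors had a median of -0.28 and a camera adjusted p = 0.000396 (adjusted p = 0.24 with an estimated correlation), with 7 members at an unadjusted p under 0.05 and 0 called by edgeR, DESeq2 and limma-voom. The p53 list had a median of 0.02 and a mean of -0.02 (camera adjusted p = 0.547, upward). Survival genes had 0.03 and -0.19 (0.623, downward), and pro-apoptotic genes a median of -0.09 (0.918) that turned to 0.04 without PBS 3.

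The medians of neuronal lists in Gel versus PBS lay between -0.10 and 0.11. Amacrine genes had a median of 0.11 and a camera adjusted p = 0.000976 (adjusted p = 0.22 with an estimated correlation), while bipolar genes (0.02, camera adjusted p = 0.135) and horizontal genes (0.11, 0.151, and 0.0175 without PBS 2) did not pass. Rod genes had a median of 0 and a mean of -0.01 (camera adjusted p = 0.487, upward, 0.000516 without PBS 3 and 0.0226 without Gel 1, with medians of -0.05, -0.08 and -0.09 without PBS 1, PBS 2 or Gel 2). Cone genes had a median of -0.10 (0.241, and 0.0307 without PBS 2). Ganglion cell genes had a median of 0 and a mean of -0.03 (0.97, upward by camera and downward by fry). Oxidative phosphorylation genes had a median of -0.13 (camera adjusted p = 0.558), passed lower without PBS 1 (-0.24, 0.017) or PBS 2 (-0.27, 0.0362), and passed higher without PBS 3 (0.22, 8.83e-06). Clock genes had a median of 0.10 (camera adjusted p = 0.0213, and 0.6 as adjusted p with an estimated correlation), lost without PBS 3 (0.488) or Gel 1 (0.582). Immediate early genes had a median of -0.21 (camera adjusted p = 0.0736) and passed without PBS 2 (0.0287), PBS 3 (0.00895) or Gel 2 (0.00638). Unfolded protein genes (median -0.04, 0.487), mitochondrially encoded genes (-0.03, 0.784, and 0.0345 without Gel 3), lens genes (0.22, 0.151, and 0.0197 without PBS 3 and 0.00455 without Gel 2), lymphocyte genes (0.23, 0.807) and skeletal muscle genes (-0.16, 0.151) did not pass. Erythrocyte genes had a median of -1.59 with all 5 lower adjusted over the list alone (camera adjusted p = 1.63e-05, and 0.22 as adjusted p with an estimated correlation), Hba-a1 at -1.77 ± 0.42 and Hbb-bs at -1.79 ± 0.43 (edgeR adjusted p = 0.576 each, and 0.012 and 0.00569 without PBS 2). Pigment epithelium genes had a median of 0.57, with Lrat (1.85 ± 0.50) and Stra6 higher and Mlana (-2.74 ± 0.81) lower adjusted over the list alone (camera adjusted p = 0.00753, 0.61 as adjusted p with an estimated correlation, 0.481 without PBS 1 and 0.155 without PBS 2). Corneal genes had a median of 3.92 (camera adjusted p = 0.405), with Krt12 at 3.92 ± 1.50 (-1.77 without Gel 2) and Krt15 at 4.83 ± 1.32 (1.87 without Gel 2). In total camera called 19 of 38 lists, 15 lower and 4 higher, with 0 for an estimated correlation (smallest adjusted p = 0.22) and 0 for fry (smallest 0.0757), which called 5 in its test for change in either direction.

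**Figure D2:**
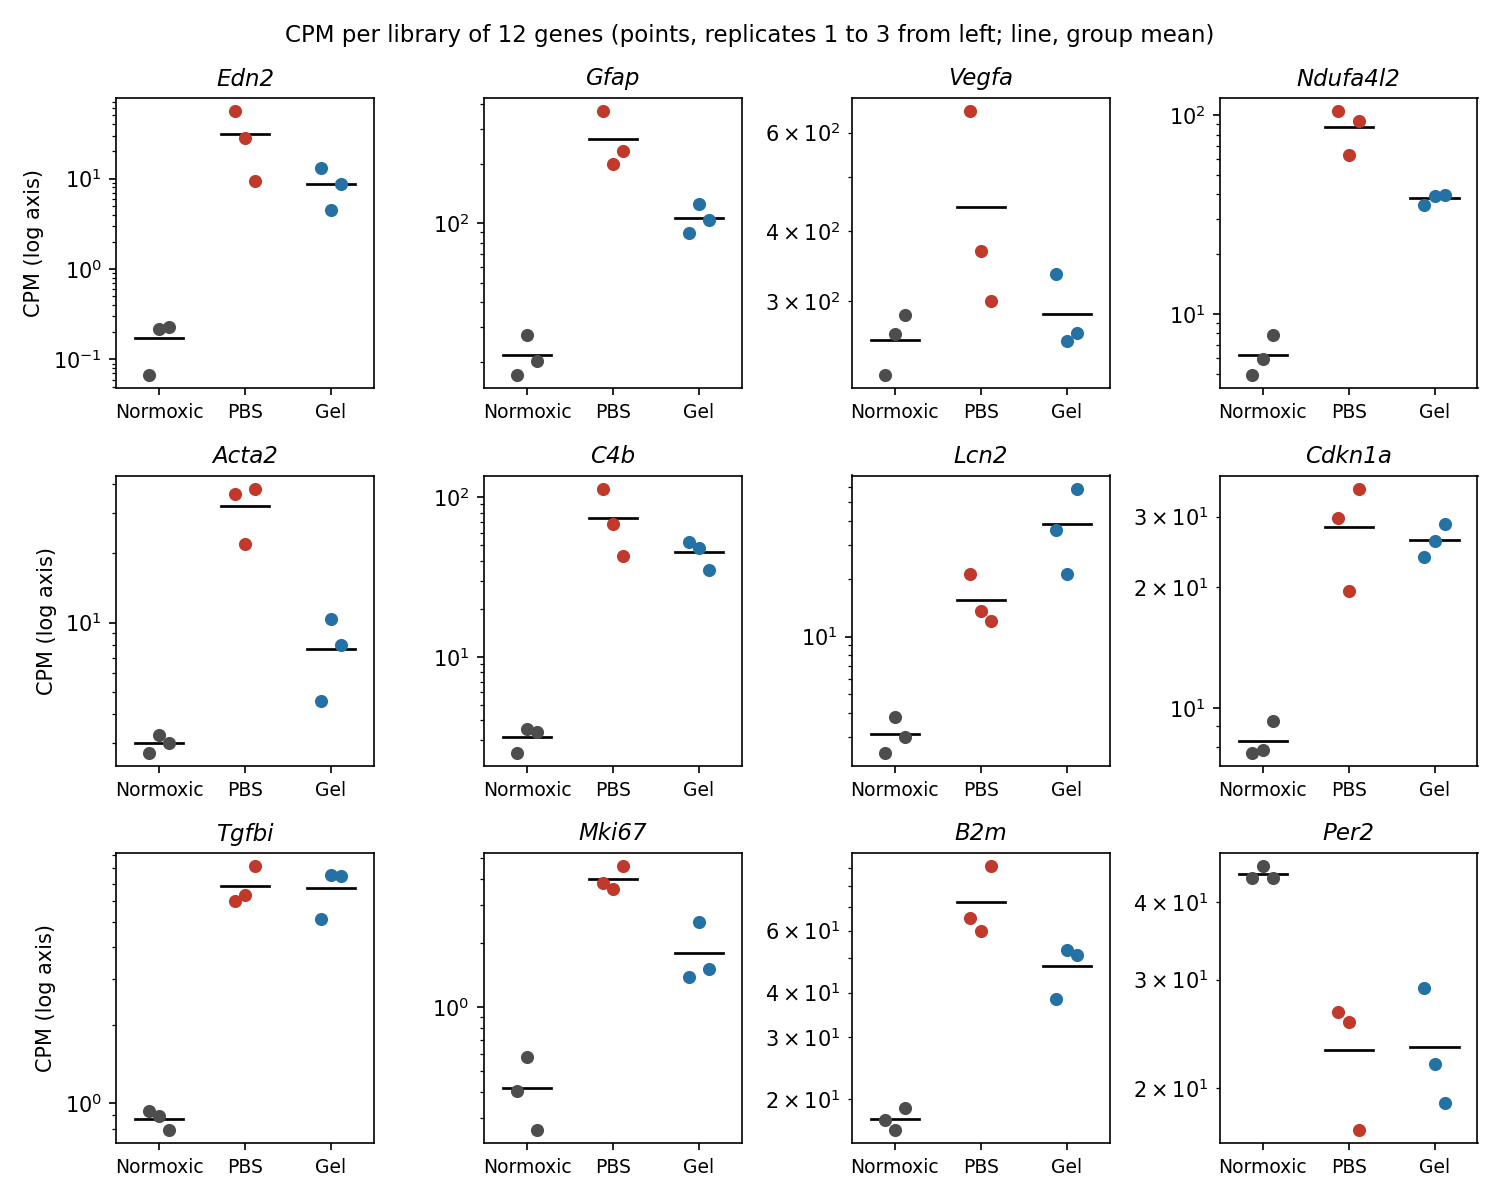
CPM (log axis) of 12 genes in each library, with points for replicates 1 to 3 from left to right in each group and a line at the group mean. Edn2 rises from a mean of 0.171 CPM in Normoxic to 31.2 CPM in PBS and lies at 8.78 CPM in Gel, while Cdkn1a lies at 28.2 CPM in PBS and 26.2 CPM in Gel.

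Gel and Normoxic retinas were compared to see how far OIR retinas with the hydrogel stood from retinas without OIR. The largest increases were Esm1, at 94 counts over the Gel libraries and 1 over the Normoxic libraries (count ratio 88.3, 95% counting interval 15.5 to 3530), Edn2 (8.78 ± 4.32 and 0.171 ± 0.0902 CPM, SD, n = 3), C4b (log2 fold change 3.85 ± 0.34, SE), Fgf2os (3.85 ± 0.67, with Fgf2 at 1.79 ± 0.25), Steap4 (3.72 ± 0.51), the membrane protein Emp1 (3.66 ± 0.57), Lcn2 (3.64 ± 0.37) and Lad1 (3.59 ± 0.54). Emp1 was at 2.81 without Gel 2, Steap4 at 3.09 without Gel 3 and Fgf2os at 5.36 without Normoxic 2. Among the largest decreases were Actn2 (-1.78 ± 0.36), the immediate early gene Fos (55.7 ± 6.61 to 17.7 ± 6.15 CPM), P2rx2 (-1.58), Arsi (-1.22), Dusp1 (-1.17), Pik3r5 (-1.07) and Lrp2bp (-1.01). The edgeR adjusted p was 0.0005 to 0.0492 for these genes. In all, edgeR called 245 of 17362 genes, 195 higher and 50 lower (79.6% higher), with 2298 at an unadjusted p under 0.05 and 24.0% of genes without overlap, where chance gives 10%. The count was 735 without PBS 3 (67.2% higher), 52, 47 and 98 without Normoxic 1, 2 and 3 (90.4%, 93.6% and 90.8% higher), 91 without Gel 2 (91.2%) and 95 without Gel 3. It was 769 with DESeq2 (69.6% higher), 2831 with limma-voom (52.0%) and 643 with only the 6 libraries (66.6%). The edgeR calls that 1 library could end were those of Edn2 (Normoxic 1 or 2, adjusted p up to 0.0721), Fgf2 (Normoxic 1 or 2, 0.054), Fgf2os (Normoxic 1, Gel 2 or Gel 3, 0.125), Steap4 (Normoxic 2, 0.0512), Emp1 (any Normoxic library, 0.0736) and Lad1 (Normoxic 1 or 3, 0.0735). It also ended those of Dusp1 (Normoxic 1, Normoxic 2 or Gel 2, 0.0981), of Fos (any Normoxic library, Gel 1 or Gel 3, 0.14), of Actn2 (any Normoxic or Gel library or PBS 2, 0.156), of P2rx2 (any Normoxic library, PBS 2, Gel 1 or Gel 3, 0.182), of Arsi (any library but PBS 3 and Gel 1, 0.206), of Pik3r5 (any Normoxic or Gel library, 0.134) and of Lrp2bp (any Normoxic library, PBS 2, Gel 2 or Gel 3, 0.171).

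Vessel, glial and immune genes were higher in Gel than in Normoxic. Gfap rose 4.90-fold (to 106 ± 18.2 CPM, SD, n = 3, edgeR adjusted p = 0.00187), Serpina3n 8.89-fold, C3 7.84-fold (1.41 ± 0.288 to 11.1 ± 1.90 CPM) and Csf1r 2.44-fold. C1qa rose by 1.71 ± 0.27, B2m by 1.44 ± 0.18, Igfbp3 by 1.75 ± 0.18 and Col4a1 by 1.24 ± 0.17 on the log2 scale. Of the glial reactivity genes 10 rose (18 higher and 1 lower adjusted over the list alone). Their median was 1.79, with a camera adjusted p = 5.38e-19 (adjusted p = 0.1 with an estimated correlation). Of the complement genes 11 rose (14 adjusted over the list alone). Their median was 1.65, with a camera adjusted p = 5.38e-19 (adjusted p = 0.035 with an estimated correlation). Of the microglia markers 9 rose (19 adjusted over the list alone). Their median was 1.29, with a camera adjusted p = 4.7e-19 (adjusted p = 0.097 with an estimated correlation), and of the sprouting genes 10 (16 adjusted over the list alone). Their median was 1.13, with a camera adjusted p = 4.37e-17 (adjusted p = 0.056 with an estimated correlation). Of the endothelial markers, Tie1 (1.21 ± 0.20), Vwf (0.94 ± 0.16), Cdh5 (0.86 ± 0.16) and Eng (0.69 ± 0.14) rose, 4 in all (14 adjusted over the list alone). Their median was 0.60, with a camera adjusted p = 5.46e-09 (adjusted p = 0.13 with an estimated correlation). Pecam1, at 27.7 ± 2.67 CPM and 0.81 ± 0.17, had an edgeR adjusted p = 0.0503 (0.0394 without PBS 2, 0.00216 without PBS 3, range 0.00162 to 0.203). The pericyte list had a median of 0.60 (8 higher adjusted over the list alone, camera adjusted p = 9.22e-07, and 0.1 as adjusted p with an estimated correlation), with 0 called by edgeR over all genes, 8 at an unadjusted p under 0.05, 7 by DESeq2 and 8 by limma-voom. Its Acta2 differed by 1.37 ± 0.30 (edgeR adjusted p = 0.0537, range 0.000403 to 0.209, and 0.041, 0.0174 and 0.0135 without PBS 2, PBS 3 and Gel 1). Interferon genes had a median of 0.90 (18 higher adjusted over the list alone, camera adjusted p = 1.5e-11, and 0.22 as adjusted p with an estimated correlation), with 0 called by edgeR over all genes, 19 at an unadjusted p under 0.05, 11 by DESeq2 and 19 by limma-voom. The interferon list mean was 0.53, 1.18 and 0.94 in Gel 1, 2 and 3, beside -0.59 in Normoxic 3. Gfap and Pdgfra (0.63) rose among the astrocyte markers (3 adjusted over the list alone). Their median was 0.20, with a camera adjusted p = 0.0122 (adjusted p = 0.16 with an estimated correlation), and the Müller homeostatic list had a median of -0.04, a mean of 0.06 and a camera adjusted p = 0.973 (0 called by edgeR and DESeq2, 4 at an unadjusted p under 0.05, 6 by limma-voom). Of the lymphocyte genes Cd8a rose (1.87), median 0.34, camera adjusted p = 0.1 (0.0382 without Normoxic 1, 0.0353 without Gel 3). Leaving out 1 library ended the edgeR calls of Col4a1 (Normoxic 2, adjusted p = 0.0587), C1qa (Normoxic 1, Normoxic 2 or Gel 2, up to 0.0897), Vwf (Normoxic 2, Gel 2 or Gel 3, 0.0735), Tie1 and Cdh5 (Normoxic 1, Normoxic 2, Gel 2 or Gel 3, 0.1 and 0.17), Cd8a (any Normoxic library, Gel 2 or Gel 3, 0.126), Pdgfra (those or PBS 2, 0.202) and Eng (any library but PBS 1 and PBS 3, 0.216).

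Senescence, matrix and stress lists in Gel were above Normoxic by camera, while the hypoxia list was not. Cdkn1a rose 3.16-fold (to 26.2 ± 2.43 CPM, SD, n = 3, edgeR adjusted p = 0.00306), Tgfbi 7.69-fold and Ndufa4l2 6.11-fold. Of the senescence genes Cdkn1a, B2m and the chromatin protein Hmgb2 (1.97 ± 0.33) rose, 3 in all (4 adjusted over the list alone). Their median was 0.25, with a camera adjusted p = 7.5e-05 (adjusted p = 0.12 with an estimated correlation). Among the 3 risers only Cdkn1a is a cell cycle inhibitor, so the rise of the list does not by itself show senescent cells. Of the secretory factors 4 rose, among them Igfbp3, Icam1 (2.06) and Tnfrsf1b (1.04) (9 higher and 1 lower adjusted over the list alone). Their median was 0.25, with a camera adjusted p = 9.95e-06 (adjusted p = 0.13 with an estimated correlation). Of the p53 targets Cdkn1a and Phlda3 (0.97) rose (6 adjusted over the list alone). Their median was 0.11, with a camera adjusted p = 0.000836 (adjusted p = 0.13 with an estimated correlation). Survival genes had a median of 0.14 (camera adjusted p = 0.0631, 0.0382 without Normoxic 1 and 0.0241 without Gel 1, 2 higher adjusted over the list alone). Pro-apoptotic genes had 0.23 (0.0122, and 0.14 as adjusted p with an estimated correlation, 3 higher adjusted over the list alone). Each had 0 called by edgeR over all genes, 4 and 8 at an unadjusted p under 0.05, 2 and 2 by DESeq2 and 3 and 6 by limma-voom. Of the NF-kB genes Icam1 rose (5 adjusted over the list alone). Their median was 0.53, with a camera adjusted p = 8.34e-05 (adjusted p = 0.12 with an estimated correlation). Matrix genes had 8 risers (16 adjusted over the list alone). Their median was 0.73, with a camera adjusted p = 1.5e-11 (adjusted p = 0.056 with an estimated correlation). Mki67 (2.10 ± 0.36), Top2a (2.84 ± 0.56) and Ccnb1 (2.69 ± 0.55) rose among the proliferation genes (7 adjusted over the list alone). Their median was 0.63, with a camera adjusted p = 1.41e-09 (adjusted p = 0.1 with an estimated correlation). Atf3 (1.81) and Ddit3 (0.67) rose among the unfolded protein genes (8 adjusted over the list alone). Their median was 0.27, with a camera adjusted p = 1.74e-05 (adjusted p = 0.097 with an estimated correlation), and Mt2 (2.53 ± 0.23) and Mt1 (1.51 ± 0.21) among the NRF2 genes (3 adjusted over the list alone). Their median was 0.16, with a camera adjusted p = 0.00223 (adjusted p = 0.43 with an estimated correlation). Of the hypoxia genes Ndufa4l2 and Ndrg1 (0.51) rose (5 higher and 4 lower adjusted over the list alone), with a median of -0.07, a mean of 0.22 and a camera adjusted p = 0.901 in the higher direction. Vegfa was at 284 ± 44.2 CPM in Gel (0.15 ± 0.25, edgeR adjusted p = 0.827). The hypoxia list mean was 0.06, 0.22 and 0.22 in Gel 1, 2 and 3. Of the fibroblast genes Pdgfra rose (3 adjusted over the list alone). Their median was 0.44, with a camera adjusted p = 0.025 (adjusted p = 0.43 with an estimated correlation), lost without Normoxic 1 (0.0557), Normoxic 3 (0.2), Gel 2 (0.112) or Gel 3 (0.0904). Without 1 library, edgeR no longer called Hmgb2 (any Normoxic library or Gel 3, adjusted p up to 0.1), Mki67 (any Normoxic library or Gel 2, 0.108), Icam1 (Normoxic 1, Normoxic 2, Gel 2 or Gel 3, 0.139), Tnfrsf1b (any Normoxic or Gel library or PBS 2, 0.143), Top2a (Normoxic 1, Normoxic 3, PBS 2, Gel 2 or Gel 3, 0.177), Ccnb1 (any Normoxic or Gel library or PBS 2, 0.198), Pdgfra (above), Phlda3 (any Normoxic library, Gel 2 or Gel 3, 0.223), Ddit3 (any library but PBS 3 and Gel 3, 0.247) and Ndrg1 (any library but PBS 3, 0.257).

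Bipolar, amacrine and ganglion cell lists in Gel were lower than in Normoxic by camera, and the rod list was higher. Bipolar genes had a median of -0.32 (camera adjusted p = 4.07e-05, and 0.056 as adjusted p with an estimated correlation), amacrine genes -0.22 (1.63e-05, and 0.1) and ganglion cell genes -0.17 (0.000491, and 0.3, with 0.0523 without Gel 1). In these, 5, 2 (Slc6a9 among them) and 3 (Nefm, Nefh and Ebf3) were lower adjusted over the list alone, with 0 called by edgeR over all genes, 7, 7 and 5 at an unadjusted p under 0.05, 3, 2 and 1 by DESeq2 and 8, 7 and 4 by limma-voom. Horizontal cell genes had a median of -0.14 (camera adjusted p = 0.295). Of the rod genes Nr2e3, a transcription factor of rods, rose (620 ± 28.9 to 1020 ± 100 CPM, edgeR adjusted p = 0.0405), with a list median of 0.11 and a camera adjusted p = 0.0187 (adjusted p = 0.56 with an estimated correlation) that was lost without Normoxic 1 (0.0573), Normoxic 2 (0.0558) or Gel 2 (0.188). The rod mean was -0.03, 0.28 and 0.20 in Gel 1, 2 and 3. Cone genes had a median of 0.16 (camera adjusted p = 0.0506, and 0.0366, 0.0461, 0.0367 and 0.019 without Normoxic 1, PBS 2, PBS 3 and Gel 1). Of the immediate early genes Fos and Dusp1 fell (1 higher and 5 lower adjusted over the list alone). Their median was -0.23, with a camera adjusted p = 0.0252 (adjusted p = 0.44 with an estimated correlation), lost without Normoxic 2 (0.0621) or Gel 1 (0.15). Of the clock genes Per2 fell (44.5 ± 1.11 to 23.3 ± 5.24 CPM), with a median of 0.01, a mean of -0.03 and a camera adjusted p = 0.892 in the lower direction. Cholesterol synthesis genes had a median of 0.01 and a mean of -0.05 (camera adjusted p = 0.637, lower, 0 called by edgeR and DESeq2, 1 at an unadjusted p under 0.05 and by limma-voom). Pigment epithelium genes had a median of 1.01 (7 higher adjusted over the list alone, camera adjusted p = 0.000593, and 0.43 as adjusted p with an estimated correlation), with 0 called by edgeR over all genes, 7 at an unadjusted p under 0.05, 3 by DESeq2 and 8 by limma-voom. Among these Lrat, which esterifies vitamin A, differed by 2.40 ± 0.52 (edgeR adjusted p = 0.0522, 0.00998 without PBS 3, range 9.3e-05 to 0.223) and Rpe65, the isomerase of the visual cycle, by 2.20 ± 0.60 (0.113, 0.0268 without PBS 3, range 0.015 to 0.355). Oxidative phosphorylation genes (median 0.17, camera adjusted p = 0.117, and 0.0187 without PBS 3 and 0.00188 without Gel 1), mitochondrially encoded genes (0.14, 0.406, and 0.033 without Gel 1), lens genes (-0.59, 0.637), erythrocyte genes (-0.14, 0.761), corneal genes (2.71, 0.753, with Krt12 at 3.78 ± 1.49 and Krt15 at 2.71 ± 1.11, and at -1.93 and -0.25 without Gel 2) and skeletal muscle genes (-0.15, 0.706) did not pass. Calls by edgeR that ended without 1 library were those of Nr2e3 (any Normoxic or Gel library or PBS 2, adjusted p up to 0.19), Per2 (any Normoxic library, PBS 2, Gel 2 or Gel 3, 0.18), Fos and Dusp1 (both above).

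**Figure D3:**
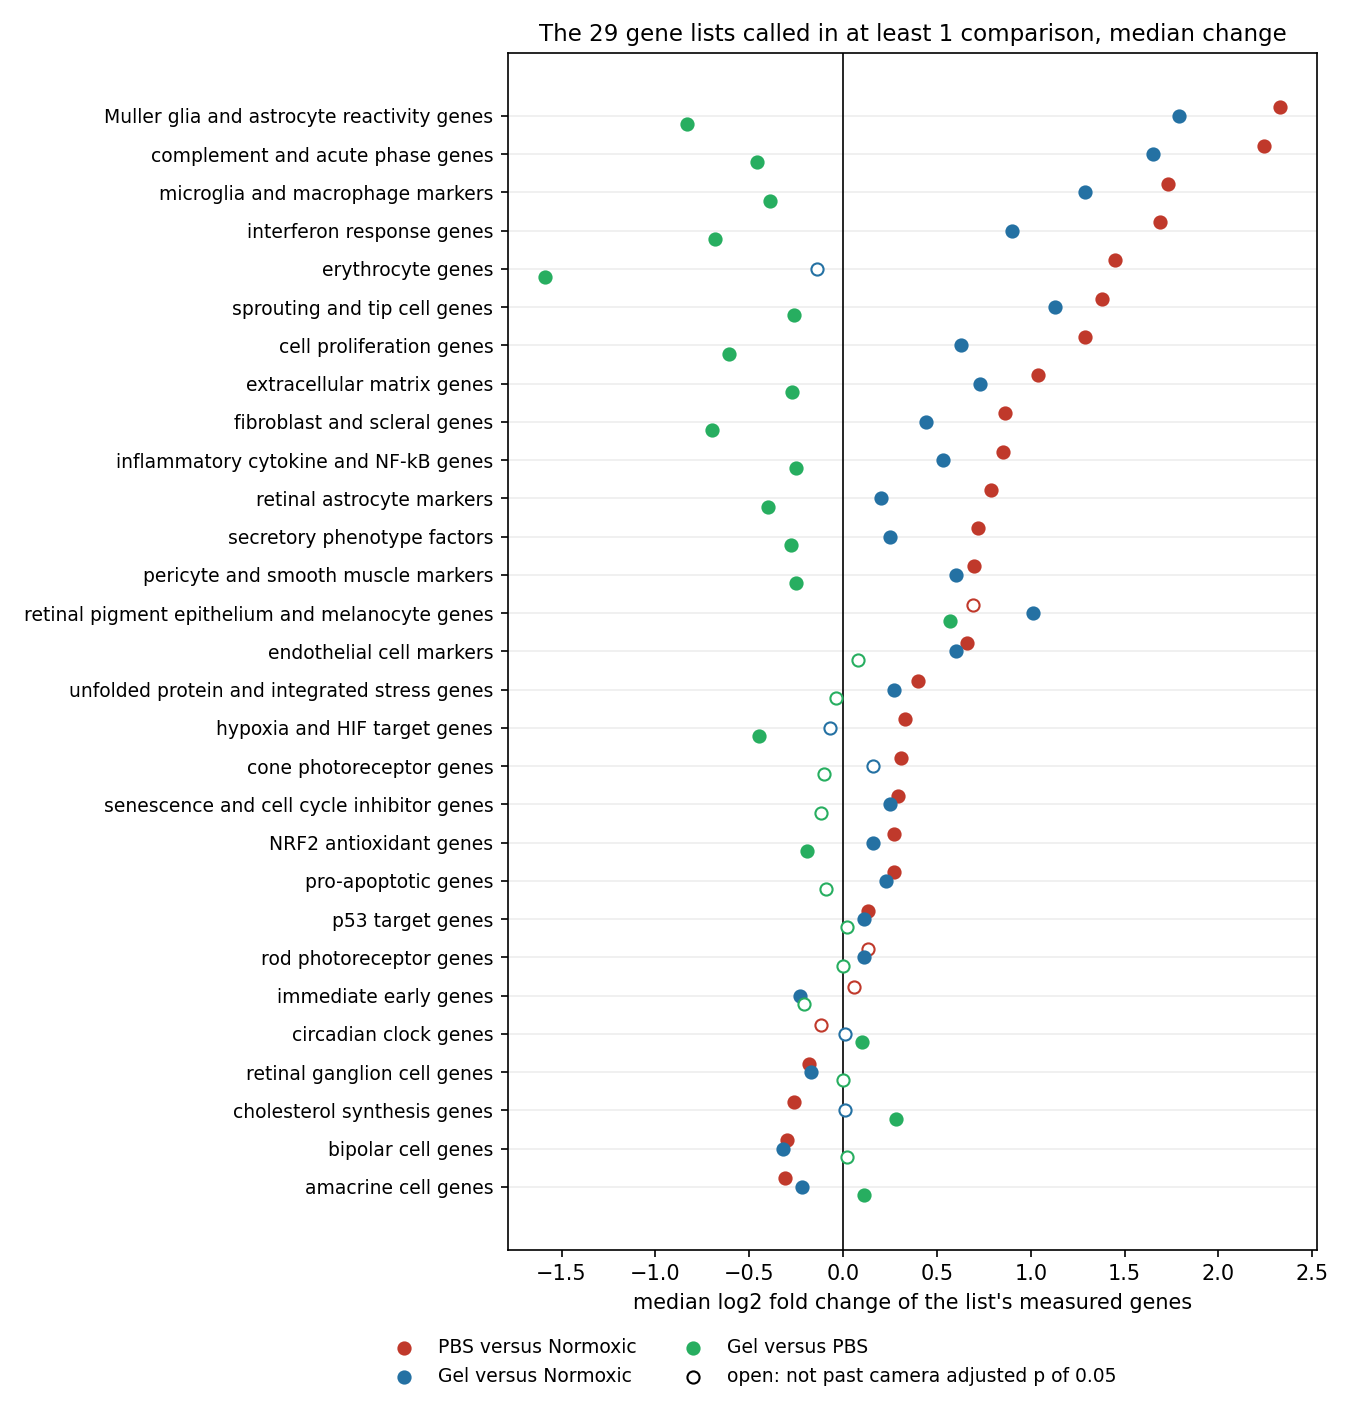
Median log2 fold change of the gene lists called by camera in at least 1 comparison, with 1 point per comparison and a filled point where the list was called. Glial reactivity genes lie at 2.33 in PBS versus Normoxic, 1.79 in Gel versus Normoxic and -0.83 in Gel versus PBS.

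The changes of PBS and Gel against Normoxic overlapped. Of the 748 genes higher in PBS, 178 were also higher in Gel, where 8.4 would be shared by chance, and of the 353 lower, 38 were also lower, where 1.02 would be shared. Both comparisons use the same 3 Normoxic libraries. These cannot be split into 2 sets of at least 2, so part of the excess may come from the shared controls. In simulated data without any group difference the correlation of the 2 sets of log2 fold changes was 0.50, against 0.81 here, and their covariance 0.0421, against 0.197 here. The median log2 fold change of the genes higher in PBS was 1.47 in PBS versus Normoxic and 0.89 in Gel versus Normoxic, and of those lower -0.63 and -0.40. Of the 1101 genes called in PBS versus Normoxic, 1019 (92.6%) had the opposite sign in Gel versus PBS, 692 of 748 and 327 of 353. The PBS libraries serve both comparisons, so opposite signs arise in excess without any effect. In 30 simulated data sets with Gel drawn from the PBS means the share was 65.8% (64.4% to 67.9%). The log2 fold change covariance was -0.0417 there and -0.11 here. Genes at an unadjusted p under 0.05 in Gel versus PBS numbered 961, against 852.6 (806 to 891) simulated. Genes also move together within libraries (length trend), which may widen these ranges, so chance stays open.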

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

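Groups of 3 libraries were not tested for single samples far from the others. Both tests of why PBS 3 stands apart were chosen after the result was seen, the bound on the second after its own value, and so was the removal of the length trend, while what it would have to leave of the lists was set beforehand. The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. In PBS versus Normoxic, 1 of the 10 splits called as many genes as the real one (1101 genes, highest other 0), in Gel versus Normoxic also 1 of 10 (245 genes, highest other 0), and in Gel versus PBS 10 of 10 (0 genes, highest other 2508, with 961 at an unadjusted p under 0.05 in the real split, 60 called by DESeq2 and 11 by limma-voom). The split of PBS 1, PBS 2 and Gel 1 against PBS 3, Gel 2 and Gel 3 is the one that called 2508 genes by edgeR, and 1698 with the length trend removed, which points to a structure of the samples across both groups that the length trend covers only in part.

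In Gel versus PBS 19 gene lists were called by camera with a preset correlation, most toward their Normoxic level, though 0 were called with an estimated correlation (smallest adjusted p = 0.22) or by fry (smallest 0.0757). Shared PBS libraries do not account for all of the opposite signs. With none serving both comparisons, 73.5%, 72.1% and 78.5% of the PBS versus Normoxic calls had the opposite sign in Gel versus PBS. With the length trend removed, 89.5% (17 of 19) were still called in the same direction. Without each PBS library in turn, 100% (19 of 19) kept their direction and 15 were called in all 3 fits. Neither decides the cause: the calls rest on the preset correlation, and fits without a PBS library keep the others. A smaller response in Gel retinas, from the drug, its carrier or a milder retinopathy in those animals, stays open as a hypothesis, and so does the structure of the samples above.

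PBS 3 lies apart from PBS 1 and PBS 2, with higher rod, oxidative phosphorylation and pigment epithelium genes. Its difference from them followed gene length (Spearman -0.49 across genes, against -0.05 to 0.03 in Normoxic libraries), which is consistent with a difference in RNA or library preparation. A stronger response to oxygen in that retina cannot be told apart from the spread of the PBS libraries: its glial reactivity list differed by -0.68 from the other 2, less than these differed from each other (3.14 in PBS 1, 2.28 in PBS 2, 2.03 in PBS 3), while its microglia (2.04, against 1.42 and 1.49), proliferation (1.89, against 1.24 and 1.21) and endothelial lists (0.77, against 0.11 and 0.39) were higher. What produced the length trend was not tested.

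Pigment epithelium genes were higher in Gel than in Normoxic retinas by camera (median 1.01), but not with an estimated correlation (adjusted p = 0.43) or by fry (adjusted p = 0.26). Their median pairwise correlation across the 9 libraries was 0.62, against a median of 0 and a 95th percentile of 0.12 in 1000 random lists, which is consistent with a varying amount of pigment epithelium carried over at dissection. The length trend does not account for the difference, since the median was 1.03 without it. In Gel versus Normoxic the visual cycle and transport genes differed by 1.01 to 2.40 (Lrat 2.40, Rpe65 2.20, Ttr 1.89, Rgr 1.73, Rdh5 1.32, Slc16a8 1.28, Stra6 1.01) and the melanin genes by -0.82 to 1.06 (Tyr 1.06, Oca2 0.95, Dct 0.56, Tyrp1 0.44, Slc45a2 -0.41, Pmel -0.45, Mlana -0.82), and the channel gene Best1 by -0.22, with 0 of them called by edgeR (7 of the list at an unadjusted p under 0.05, 3 by DESeq2, 8 by limma-voom). Carry-over stays open, and so does an effect of the treatment on the pigment epithelium, which was not tested.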

How the results depend on the processing

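The length trend removals and the surrogate variable were chosen after the data were examined. Of 2550 values of named genes under the alternatives, 2155 kept their direction and their side of the threshold, 318 were no longer called, 71 became called and 6 reversed. Of 1704 values of lists, 1475 kept both, 124 were no longer called, 43 became called and 62 reversed in the direction of the test, which need not be the sign of the median. No called gene changed sign. Where a value moved or reversed, the cause was not tested, except that left-out libraries mean fewer samples and a minimum fold change means fewer genes.

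Genes called in PBS versus Normoxic numbered 1101, and 1858 with DESeq2, 1928 with limma-voom, 5085 with 1 surrogate variable, 599 at a log2 fold change of at least 1, and 455 to 1184 with 1 library left out (lowest without Normoxic 2, highest without PBS 2). In Gel versus PBS edgeR called 0 (961 at an unadjusted p under 0.05), 24 with no filter, 3 with the length trend removed, 213 with the surrogate variable and 0 to 12 with 1 library left out (highest without PBS 2), and DESeq2 called 60 and limma-voom 11. In Gel versus Normoxic the count was 245, and 389 with no filter, 437 with the length trend removed, 2522 with the surrogate variable, 769 with DESeq2, 2831 with limma-voom, 643 with the 6 libraries, 156 at a log2 fold change of at least 1 and 47 to 735 with 1 library left out (lowest without Normoxic 2, highest without PBS 3). The surrogate variable was estimated from the same libraries' residuals, so its counts can be too high. Lists called by camera numbered 25, 19 and 24 in PBS versus Normoxic, Gel versus PBS and Gel versus Normoxic, and 4, 0 and 1 with an estimated correlation. By fry 23, 0 and 18 were called. The share of oppositely changed genes was 92.6%, and 90.2% with the length trend removed, 95.2% at a log2 fold change of at least 1 and 88.1% to 95.4% with 1 library left out. Of the 132 called genes named, 72 (without Normoxic 1) to 122 (without PBS 3) kept their call with 1 library left out, 76 without Normoxic 2 and 86 without Normoxic 3.

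The values do not settle whether the replicate numbers pair the samples: 4 of 9 libraries were closest to one with their own number, and the deviations of PBS and Gel libraries correlated at 0.33, -0.21 and 0.36. With the replicate block 1050, 0 (by edgeR, 919 at an unadjusted p under 0.05) and 227 genes were called in PBS versus Normoxic, Gel versus PBS and Gel versus Normoxic, and 383 in the last with the length trend also removed. Ganglion cell genes had a median of 0 in Gel versus PBS with the replicate block.

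Lists with another camera direction than in the main test had these medians. With the length trend removed they were oxidative phosphorylation 0.03 and mitochondrially encoded genes -0.13 in PBS versus Normoxic. In Gel versus PBS they were pro-apoptotic -0.03, unfolded protein 0.03, oxidative phosphorylation 0.03 and mitochondrially encoded genes 0.09, and in Gel versus Normoxic hypoxia -0.07, clock 0.02 and mitochondrially encoded genes -0.01. With a 1 CPM filter, ganglion cell genes in Gel versus PBS were at -0.01 and survival genes at 0.06. Hypoxia genes in Gel versus Normoxic were at -0.09. By fry, ganglion cell genes in Gel versus PBS (median 0) and Müller homeostatic genes in Gel versus Normoxic (-0.04) reversed. None of these passed its test.

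Lists whose camera direction and genes whose sign reversed with 1 library left out had these ranges of medians and log2 fold changes. In PBS versus Normoxic, rod genes ranged from -0.05 to 0.19, oxidative phosphorylation from -0.08 to 0.45 and lens genes from -1.53 to 0.75. In Gel versus PBS, the ranges were endothelial -0.02 to 0.23, rod -0.09 to 0.16, cone -0.18 to 0.01, ganglion cell -0.04 to 0.16, senescence -0.26 to 0.08, p53 -0.04 to 0.09, survival -0.02 to 0.06, pro-apoptotic -0.11 to 0.04, unfolded protein -0.14 to 0.02, oxidative phosphorylation -0.27 to 0.22 and mitochondrially encoded -0.31 to 0.15. Further ranges there were lens -0.23 to 0.73, lymphocyte -0.06 to 0.31, corneal -0.93 to 4.68, Cdkn1a -0.30 to 0.09, Pecam1 -0.20 to 0.17 and Krt12 -1.77 to 4.68. In Gel versus Normoxic, they were hypoxia -0.13 to 0.03, Müller homeostatic -0.11 to 0.07, cholesterol synthesis -0.07 to 0.12, clock -0.06 to 0.03, mitochondrially encoded -0.07 to 0.31, lens -1 to 0.70, erythrocyte -0.26 to -0.02, corneal -0.64 to 3.24, Krt12 -1.93 to 4.36 and Krt15 -0.25 to 3.24. Of these reversals, oxidative phosphorylation in Gel versus PBS without PBS 3 passed its test (0.22, camera adjusted p = 8.83e-06).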

Other observations

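The tests of annotated terms and of glucocorticoid targets below were chosen after the differential test was seen. Antigen presentation genes were overrepresented among the genes called higher in PBS versus Normoxic: 19 of 54 annotated genes were called where 3.22 would be by chance (Fisher adjusted p = 5.96e-09), such as B2m and Tap1. Phagosome genes (35 of 127, 7.58 by chance, Fisher adjusted p = 1.5e-12), complement and coagulation genes (21 of 50, 2.98 by chance, 2.46e-11) and matrix organization genes (42 of 193, 11.6 by chance, 5e-11) were also overrepresented. In Gel versus Normoxic, complement genes (13 of 50, 0.866 by chance, Fisher adjusted p = 4.06e-10), antigen presentation genes (6, 0.0154) and laminin interactions (5 of 10, 0.167 by chance, 5.65e-05) were overrepresented among the genes called higher.

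Genes of synapses and potassium channels were overrepresented among the genes called lower in PBS versus Normoxic. Of 189 genes of transmission across chemical synapses 24 were called lower where 4.02 would be by chance (Fisher adjusted p = 9.69e-10), such as the glutamate receptor subunit Grin1 and Gad1. Potassium channel genes (11 of 86, 1.83 by chance, 0.000445), GABAergic synapse genes (9 of 85, 1.77 by chance, 0.00633) and GABA receptor activation genes (8 of 53, 1.13 by chance, 0.00233) were also overrepresented. In Gel versus Normoxic, potassium channel genes were overrepresented among the genes called lower (5 of 86, 0.289 by chance, 0.00811). Log2 fold changes fell with gene length in both comparisons (Spearman -0.30 and -0.17). With the length trend removed, edgeR still called the neuronal genes Slc6a9, Gad1 and Grik1 lower in PBS versus Normoxic (-0.62, -0.52 and -0.45), but no longer the ganglion cell gene Ebf3 (-0.29) and the potassium channel gene Kcnj10 (-0.36). The enrichment itself was not repeated without the trend.

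Fkbp5, Zbtb16 and Arrdc2, targets of the glucocorticoid receptor, rose in both OIR groups (Fkbp5 0.98 and 1.04, Zbtb16 1.00 and 1.31, Arrdc2 1.76 and 2.09 in PBS and in Gel versus Normoxic). As a hypothesis, both groups may have had more glucocorticoid signalling than Normoxic retinas. A separate list of 20 further target genes, written after these genes were seen and before its own values, had 18 measured, 17 of them positive in PBS versus Normoxic (median 0.59, camera p = 9.14e-06, 0.0045 with an estimated correlation) and 16 in Gel versus Normoxic (median 0.51, camera p = 7.39e-07, 0.0026 with an estimated correlation), while Gel versus PBS gave a median of -0.04 (camera p = 0.802). Angptl4, Cables1, Klf15, Nfkbia, Pdk4 and Plin4 were called higher in PBS versus Normoxic and 3 of these (Cables1, Klf15 and Pdk4) in Gel versus Normoxic, but Dusp1, also a target, fell in both. Both comparisons share the Normoxic libraries, so the second is not independent support: in simulated data without group differences 66.7% of all genes had the same sign in both. Stress of handling or injection, fasting, time of day and the retinopathy itself stay open and were not tested.

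PBS 1 was the library with counts of genes on the Y chromosome (Ddx3y 964, Uty 560, Kdm5d 877, Eif2s3y 2165), while the other 8 had 0, and it had 13 counts of Xist where the others had 26979 to 43755. By these genes PBS 1 was male and the others female, so comparisons with PBS mix sexes, and sex cannot be separated from other features of PBS 1. The hypoxia list was no longer called by camera in PBS versus Normoxic without this library (median 0.22, adjusted p = 0.141), and Hmox1 (85.7, 21.2 and 37.6 CPM in PBS 1 to 3), Bcl3 (16.5, 8.11 and 2.02) and Vegfa (655, 368 and 300) were highest in it. Krt12 and Krt15, keratins of the corneal epithelium, were at 19.9 and 13.1 CPM in Gel 2.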
